A study of Mus musculus with 4 samples.

How the data were processed

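MyoD was immunoprecipitated from sonicated nuclei of primary myotubes with the antibody SC-760, per the labels' protocols. Myoblasts were grown in 20% serum and differentiated in 2% horse serum for 5 days, and libraries were amplified for 15 cycles with fragments of about 250 bp isolated from a gel, per the labels' protocols. The samples were 4: a MyoD ChIP and an input for myotubes with pyruvate, and the same for myotubes without. Groups were taken from the sample titles. An abbreviation in the names of the deposited files can be read as the opposite condition, and no measured value checks the titles, so every direction rests on them and the lists are described as labelled with or without pyruvate.

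Reads were handled with bcl2fastq 2.19, Bowtie2 2.1.0 and MACS2 2.1.1 against mouse build mm9, per the submitters' processing notes. Peaks are in 1 list per ChIP library, but whether each list came from a single calling run, how the inputs were used, the calling threshold, read filters and the source of the gene annotation are not given in the sources used here. The deposited files pair each peak with every gene region it touches, where a region is a gene body or a 2000-base flank, per the file headers and the values. Columns headed for the authors' fold enrichment hold 0 in every row with a number (0 rows differ from 0), so neither fold enrichment nor q could be used. Peak width was the only per-peak measure left. It depends on depth and fragment length as well as on binding, and no read count or depth could be computed. The input samples were not analysed here.

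Rows were reduced to distinct peaks, from 13076 rows to 11907 peaks for the library labelled with pyruvate and from 20902 to 19338 for the one labelled without. Coordinates are printed as deposited, in mm9. Peaks were counted as shared when they overlapped by at least 1 base, with the peaks of each list counted separately. Chance overlap came from 100 random circular shifts of 1 list along each chromosome. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only.

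The files named 7262 gene IDs, pooled by symbol to 7235 genes because 27 symbols had more than 1 ID, and a pooled gene had a peak if any of its IDs did. Start sites were taken from the gene bodies and strands listed in the files, which located them for 5818 genes. For the other 1417 genes only a flank is listed, and its side (upstream or downstream) is not shown by the files. Peaks in such flanks were counted as promoter-proximal together with those within 2 kb of a located start site, a departure from the design, and the counts without them are given beside the main ones. Some gene regions are very long, such as Gm20388 with 4435 kb, which adds to the share of peaks in genes. Symbols were matched to the RefSeq gene table of GRCm38.p6 for names only, with 6035 of 6147 genes that have a symbol matched and 1088 genes without one. Its 21900 protein-coding genes served as a second background.

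The 13 gene lists, 391 genes in all with 177 named in the files, were fixed before the data were examined, as were the comparisons; the closing part says which alternatives were added later. Each list's count was placed among 10000 random lists of as many genes drawn from those the files name, as a mid-rank percentile. These genes already have a peak in at least 1 list, so the percentile compares a list with other bound genes. Differences between lists were placed among random lists matched on number of peaks. The naming rule took 7 genes whatever their values (Csf3, Myod1, Myog, Ckm, Acta1, Des and Chrna1), the 10 top peaks of each list and the 10 top peaks with no overlap, and up to 4 genes per gene list and category. It was to rank by fold enrichment and ranks here by peak width. Genes outside the rule that are named (Myom2, Pygm, Med24, Psmd3 and genes in the closing part) were chosen after their values were seen.

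Alternatives tried were a reciprocal overlap of 50%, centres within 100 bases, start-site windows of 1 and 10 kb, windows of 10 and 100 kb around Csf3, located start sites alone, any peak in the gene, peaks of at least 250 bases, the widest or a random subset of the longer list (100 draws), and the RefSeq background. Motif content at peaks was not analysed here because no genome of the files' build was used. The overlap and list code was tested on partly simulated data. Of the 11907 real peaks of the shorter list, 5000 were planted in a simulated second list and 5001 were found as shared. The other simulated peaks were kept only where the same code found no overlap, so this count was nearly fixed in advance. A planted list of 200 genes, larger than any list used here, reached percentile 100 while random lists had a median percentile of 42.8. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.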

Results

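Binding of MyoD, the bHLH transcription factor that drives the muscle programme, was mapped by ChIP-seq in mouse myotubes, the multinucleated cells formed by fusing myoblasts. Primary myoblasts from C57BL/6 mice aged 2 weeks were differentiated for 5 days, and the myotubes were then kept for 24 hours in medium with or without pyruvate, a product of glycolysis that feeds the citrate cycle. There were 4 samples: 1 MyoD ChIP library and 1 input per condition. Each ChIP library had 1 deposited peak list, with 11907 peaks in the list labelled with pyruvate and 19338 in the list labelled without pyruvate, called the shorter and the longer list here. With 1 library per condition, no difference had a replicate check and no p-value was computed. Read depth is unknown, so a peak missing from a list may have been below detection there. Which condition each list stands for rests on the sample titles alone.

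The first comparison was which sites MyoD occupied in both conditions. Of the 7 genes named in advance, 3 had a promoter-proximal peak in both lists: a peak lay next to Myog, which encodes the differentiation factor myogenin, next to Des, which encodes the intermediate filament desmin, and at the start of Chrna1, which encodes the alpha subunit of the muscle acetylcholine receptor. Acta1 and Ckm had one only in the shorter list, Csf3 only in the longer and Myod1 in neither. The widest peak of either list lay in the gene Igf2bp3, which encodes an RNA-binding protein, at chr6:49085808-49087775 of mm9 (1967 bases) in the shorter list and at chr6:49085828-49087782 (1954 bases) in the longer. Of the peaks in the shorter list, 8555 overlapped the longer list by at least 1 base, or 71.8% (95% exact binomial interval 71.0 to 72.7). The same number of the longer list overlapped the shorter, or 44.2% (43.5 to 44.9).

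Circularly shifted lists overlapped at a mean of 0.439% and at most 0.605% of the shorter list, and at a mean of 0.270% and at most 0.362% of the longer. The longer list held 1.62 times as many peaks and covered 5.12 Mb against 3.29 Mb. Median peak width was 250 bases (interquartile range 205 to 315) in the shorter list and 241 bases (194 to 304) in the longer. Peaks in both lists were wider than those in 1 list, with medians of 265 against 218 bases in the shorter list and 289 against 212 in the longer. Among peaks under 200 bases wide, 54.8% of the shorter list and 19.3% of the longer overlapped the other list, and among those of 500 bases or more 91.5% and 87.5% did. The narrowest peaks were 169 bases wide in the shorter list (462 peaks) and 144 bases wide in the longer (290 peaks), and the longer list also had 461 peaks of 160 bases. The intervals cover counting error only.

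**Figure D1:**
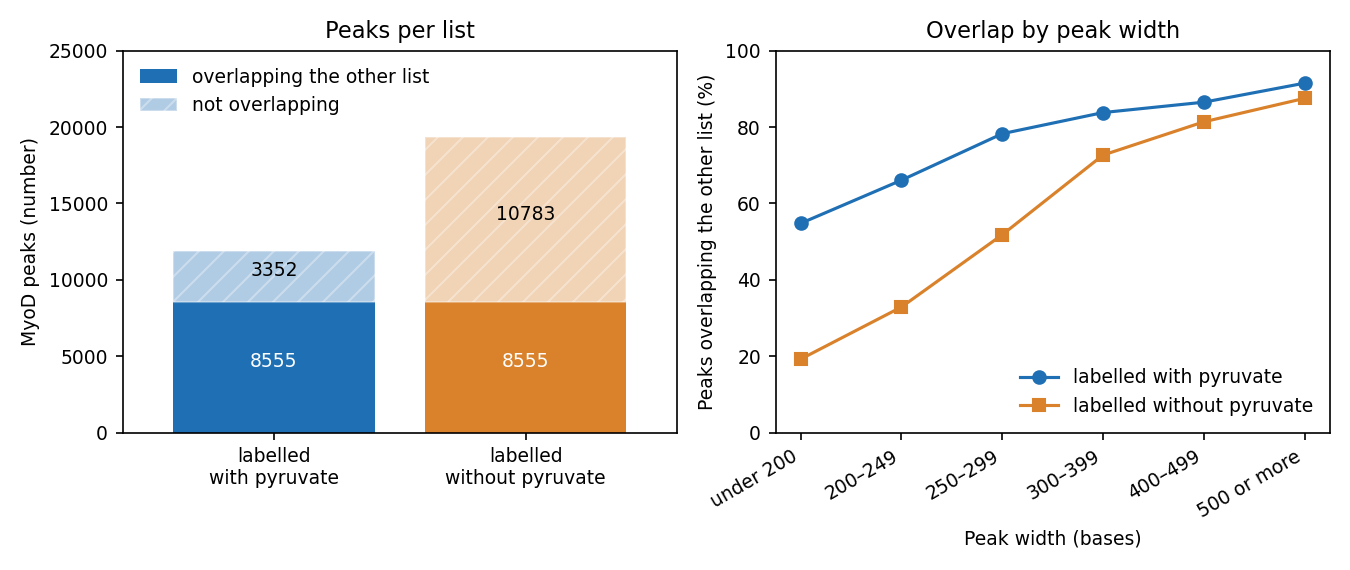
Left, number of MyoD peaks in each list, split by overlap with the other list, with 8555 overlapping in each, 3352 left in the list labelled with pyruvate and 10783 in the list labelled without. Right, percent of peaks overlapping the other list against peak width in bases, rising from 54.8% to 91.5% and from 19.3% to 87.5%, with 1 library per list and no error bars.

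**Figure D2:**
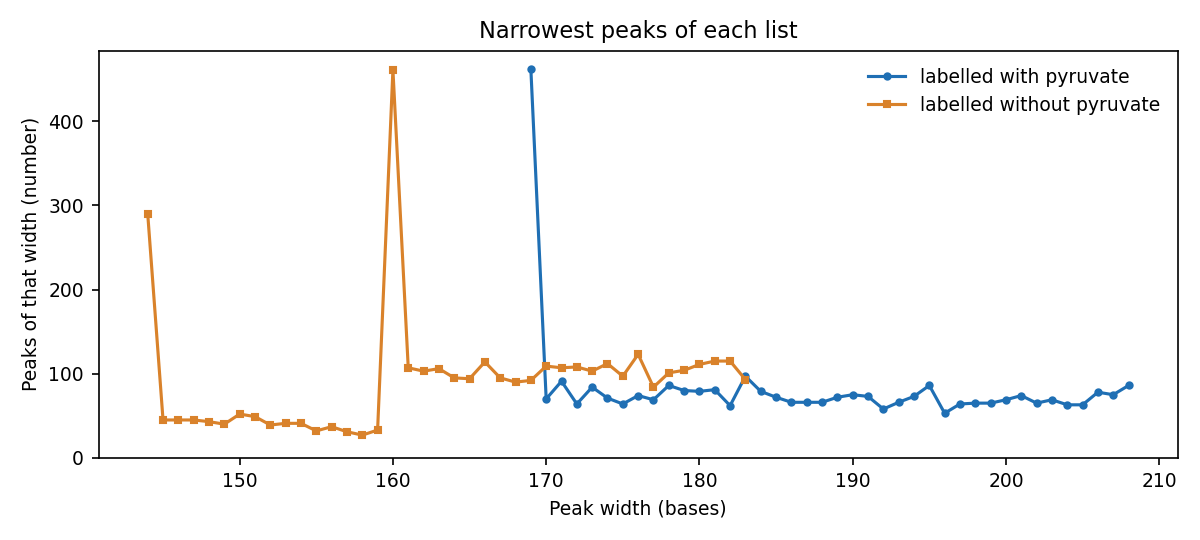
Number of peaks (vertical axis) at each of the 40 narrowest widths in bases (horizontal axis) in each list. The list labelled with pyruvate has 1 pile, 462 peaks at 169 bases, and the list labelled without has piles of 290 at 144 and 461 at 160 bases.

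Among the 10 widest peaks without a partner in the shorter list, 2 lay at muscle genes. These were a peak of 633 bases within Chrna1 (chr2:73410616-73411249, 7146 bases from the start site) and one of 590 bases upstream of Acta1, which encodes skeletal muscle alpha-actin (chr8:126419650-126420240). The others within genes lay in Shb, Sorcs2, an unnamed gene beside Ube2v1, and a gene whose symbol the file shows as 11-Sep with the description septin. The widest unpartnered peaks of the longer list lay in no gene region (chr16:94919858-94920990, 1132 bases) or in genes outside the muscle lists, among them the keratin-associated protein genes Krtap4-9 (732 bases) and Krtap9-5 (659 bases), Fbxl13 (695 bases) and Slc44a5 (662 bases). Unpartnered peaks lay a median of 19.0 kb from the nearest peak of the other list in the shorter list and 41.6 kb in the longer, with 6.92% and 3.90% of them within 1 kb. Peaks of the shorter list were measured against the longer list, so these values also follow list length and were not adjusted for it.

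The second comparison was which genes carried a promoter-proximal peak, meaning one within 2 kb of a start site or in a 2-kb gene flank whose side the files do not show. Of the genes, 1350 had such a peak in both lists, 435 only in the shorter list and 1277 only in the longer. Of flank regions whose side could be placed, 625 were upstream and 336 downstream, so some counted peaks may lie downstream. Among genes named by the rule, only a flank of unknown side was available for Myog, Des, Ckm, Mef2a, Id1, Id2, Myh3, Slc2a4 and Pgam2. The same holds for Idh3a, Sdhb, Ndufa4, Csf3, Ctf1, Fgf21, Hey1, Itgb1, Ly6a, Tubb3, Cd68 and Rpl27. Counting only located start sites gave 750, 224 and 669 genes, and counting a peak anywhere in the gene or its flanks gave 3984, 720 and 2531. With the longer list limited to as many of its widest peaks as the shorter holds, the order turned, with 728 genes only in the shorter and 559 only in the longer, and with a random subset of that size the means were 916 and 795. Both subsets also drop shared peaks, which by construction moves genes from both lists to the shorter alone. By peaks, 13.9% of the shorter list (13.3 to 14.5) and 12.5% of the longer (12.02 to 12.96) were promoter-proximal. Another 47.5% and 45.3% lay in the rest of a gene, and 37.4% (36.5 to 38.3) and 41.1% (40.5 to 41.8) lay outside all gene regions. Partnered peaks of the longer list were promoter-proximal in 14.1% of cases (13.3 to 14.8) and unpartnered ones in 11.2% (10.6 to 11.8). In the shorter list these shares were 13.98% (13.3 to 14.7) and 13.6% (12.5 to 14.8), whose intervals overlap.

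Of the 13 gene lists fixed in advance, sarcomere genes had the most members with a promoter-proximal peak in the shorter list alone in the main count. With the 10-kb window they had 3 against 4 for excitation, membrane and fusion, and at 1 kb both lists had 3. With a peak anywhere in the gene they tied with glycolysis at 4. Of 40 sarcomere genes, 11 had a proximal peak in both lists, among them the giant spring protein gene Ttn, Tpm2 and Actn3. In 5 it was seen only in the shorter list: Acta1, Tnnc1 (slow troponin C), Myh3 (embryonic myosin heavy chain), Actc1 (cardiac alpha-actin) and Myom2, and in 1, Myl1, only in the longer. At Acta1 the shorter list held 3 proximal peaks between 126418645 and 126420240 on chromosome 8, and the longer list none, while a peak downstream of the gene, 209 and 165 bases wide, was in both. Proximal peaks seen only in the shorter list were 322 bases wide at Tnnc1, 232 at Myh3 and 220 at Actc1.

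The group of 35 genes for excitation, membrane and fusion had the highest share of members with a proximal peak, 60.0% in the shorter list and 54.3% in the longer. The 17 genes in both lists included Chrna1, Dok7 (needed for the neuromuscular synapse), Cacng1 and Cdh15 (M-cadherin), whose widest proximal peaks were 794, 725, 470 and 479 bases in the shorter list and 618, 781, 518 and 421 bases in the longer. In 4 genes the proximal peak was only in the shorter list: Cacna1s, the calcium channel that senses voltage in muscle (411 bases), Bin1 (259 bases), Cav3, muscle caveolin (217 bases), and Ckm, muscle creatine kinase (190 bases, chr7:19995205-19995395). Jam2 (234 bases) and Cdon (206 bases), both cell-surface proteins of myoblasts, had one only in the longer list.

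Of 23 myogenic regulators, 5 had a proximal peak in both lists, including Myog, Mef2a, Smarcd3 and Id1, an inhibitor of bHLH factors. The Myog peak was 529 bases wide in the shorter list (chr1:136186106-136186635) and 351 in the longer. Mef2c, a partner of MyoD in activating muscle genes, had a peak at its start only in the shorter list (chr13:83642961-83643268), and a peak further inside the gene, 100636 bases from the start in the shorter list, in both. Id2 (228 bases) and Rb1 (300 bases) had a proximal peak only in the longer list. No peak of either list was assigned to the body or 2-kb flanks of Myod1 itself. Peaks further from Myod1 were not described.

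**Figure D3:**
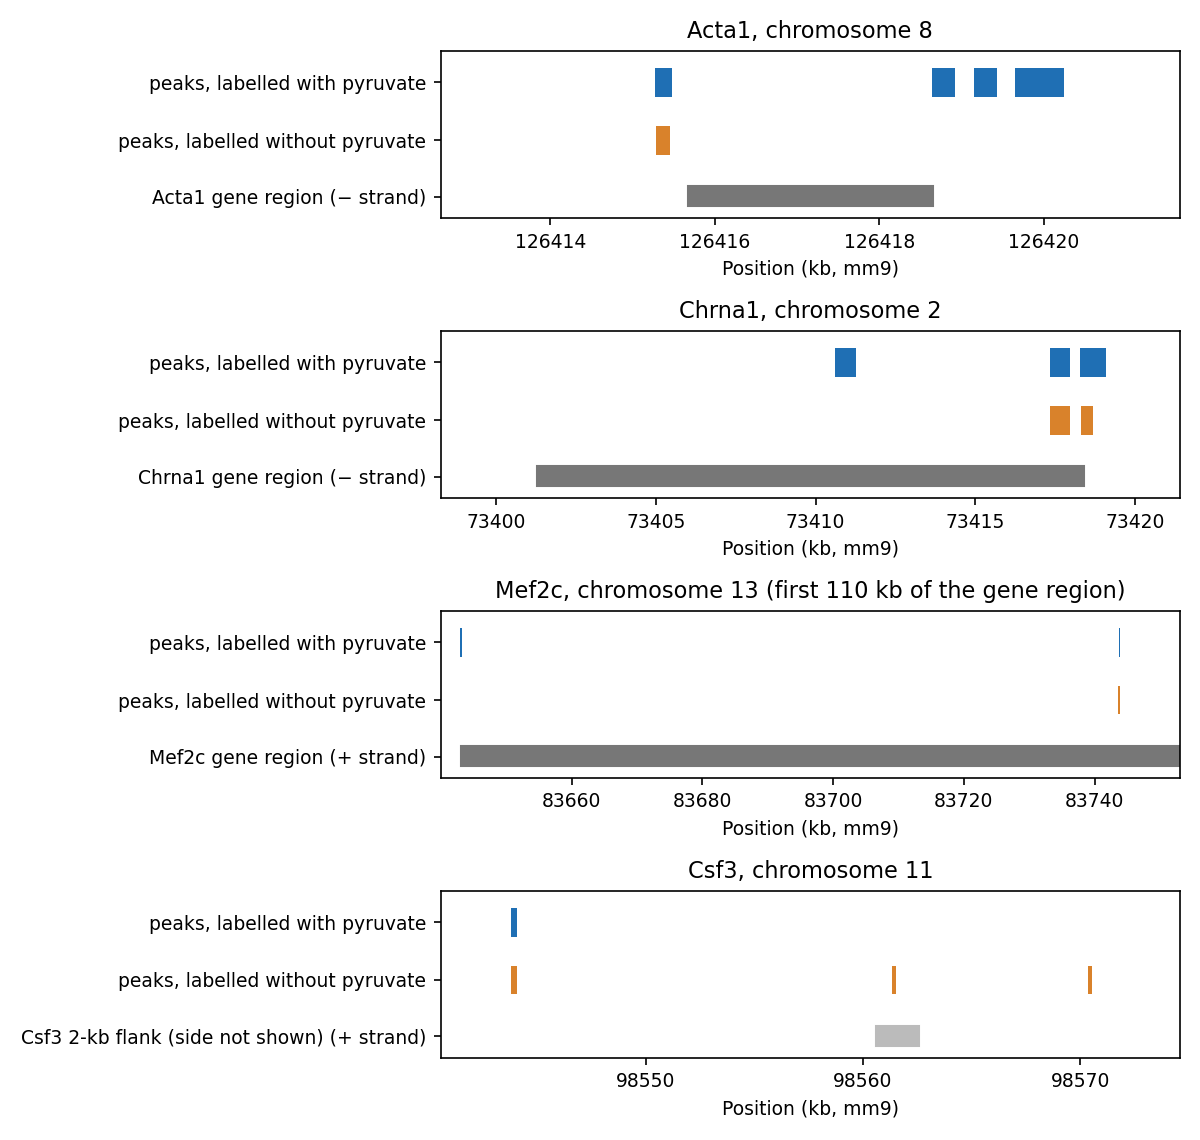
Positions in kb (mm9) of MyoD peaks at 4 genes, with the list labelled with pyruvate above, the list labelled without pyruvate in the middle and the gene region or flank given in the files below. The 3 proximal peaks of Acta1 and the start-site peak of Mef2c are in the first list only, both proximal Chrna1 peaks are in both, and the peak in the Csf3 flank is in the second only.

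Metabolic genes were the third group, given that pyruvate was the variable. Of 30 glycolysis genes, 7 had a proximal peak in both lists, including Pkm2 (pyruvate kinase), Eno1, Aldoa and the insulin-responsive glucose transporter gene Slc2a4, and 1, Pgam2 (muscle phosphoglycerate mutase, 226 bases), only in the shorter. Of 36 genes of pyruvate and the citrate cycle, 2 had one in both: Brp44, a subunit of the mitochondrial pyruvate carrier, and Pcx, pyruvate carboxylase. Idh3a (178 bases) had one only in the shorter list, and Pdk4, which inhibits pyruvate dehydrogenase (236 bases, 187 bases from its start), and Sdhb (178 bases) only in the longer. Of 32 genes of the respiratory chain and its regulators, Ndufa4, Ppard and Ppargc1b had one in both and the muscle cytochrome oxidase subunits Cox6a2 (238 bases) and Cox8b (244 bases) only in the shorter list.

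**Figure D4:**
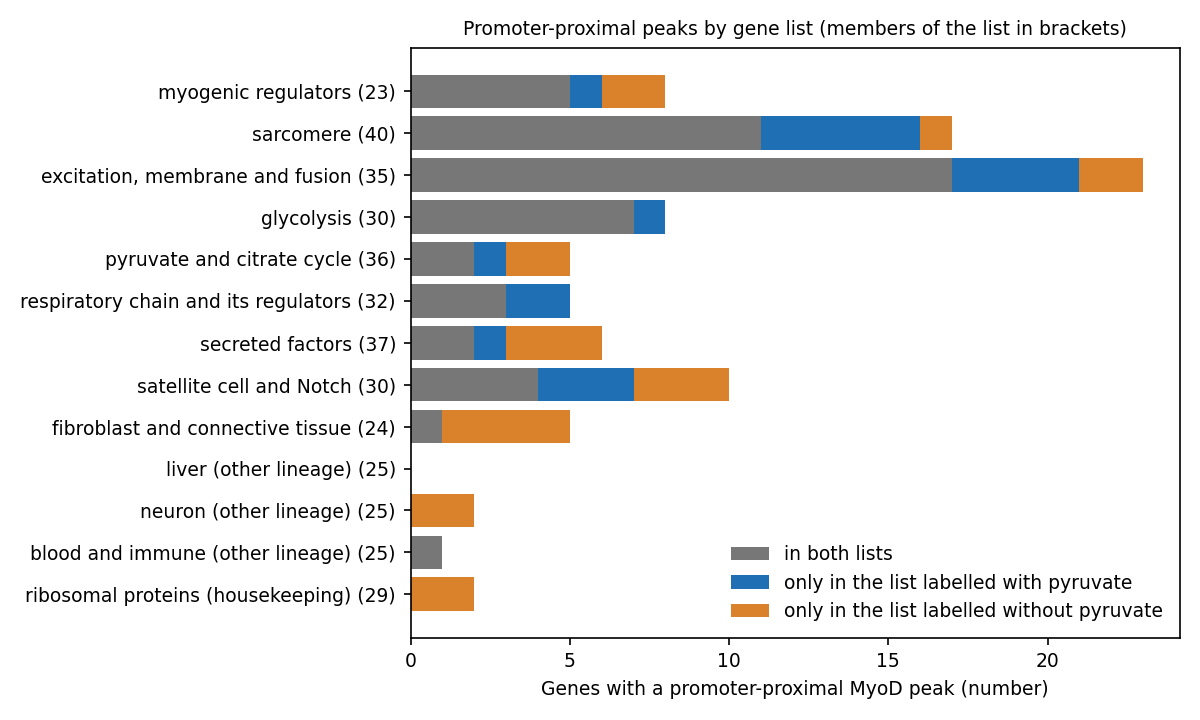
Number of genes of each fixed list with a promoter-proximal MyoD peak in both peak lists or in only 1 of them, with 1 library per condition. Sarcomere genes split as 11 in both, 5 only in the list labelled with pyruvate and 1 only in the list labelled without, and fibroblast genes as 1, 0 and 4.

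Lists of other cell types and of satellite cells were also described. Of 30 satellite cell and Notch genes, Hes1, Hes6, Cd82 and Megf10 had a proximal peak in both lists, the Notch pathway genes Rbpj, Dll1 and Hey1 only in the shorter, and Notch2, Cxcr4 and Itgb1 only in the longer. Of 24 fibroblast and connective tissue genes, 1 had one in both (Gsn) and 4 only in the longer list (Col3a1, Fbn1, Ly6a and Dpt). Among lists of other lineages, no liver gene had one, the neuronal genes Tubb3 and Nefm had one only in the longer list, and the macrophage gene Cd68 had one in both. Of 29 ribosomal protein genes, Rps18 and Rpl27 had one only in the longer list.

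Each list was described by its percentile among 10000 random lists of genes that the files name. Genes with a proximal peak were at percentile 100 in the shorter and 99.8 in the longer list for excitation, membrane and fusion, at 99.995 and 80.8 for sarcomere, 93.3 and 85.3 for myogenic regulators, 97.7 and 67.1 for glycolysis, and 99.7 and 74.7 for the respiratory chain. The other percentiles were 54.2 and 43.0 for pyruvate and the citrate cycle, 35.3 and 42.3 for secreted factors, 69.7 and 24.1 for satellite cell and Notch, and 6.36 and 49.4 for fibroblast genes. For liver they were 16.1 and 8.04, for neuron 6.81 and 35.9, for blood 53.3 and 35.7, and for ribosomal proteins 21.5 and 82.7. With a peak anywhere in the gene or its flanks, the percentiles in the longer list were 46.9 for excitation, membrane and fusion, 20.6 for sarcomere and 5.09 for glycolysis, against 99.965, 100 and 99.975 in the shorter. That measure is close to its ceiling, since 6515 of the 7235 genes have such a peak in the longer list, and against all RefSeq protein-coding genes the same counts were at 100, 100 and 98.8 there. Against that background with promoter-proximal peaks, myogenic regulators, sarcomere, excitation, glycolysis, and satellite cell and Notch genes were above percentile 99 in both lists, with 99.945 and 99.215 for the last of these. Respiratory chain genes, of which the files name 6 of 32, were at 97.4 and 58.2 against it, and at 57.8 and 5.35 with a peak anywhere in the gene. Fibroblast genes, with promoter-proximal peaks, were at 40.9 and 96.9 against it.

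The number of genes only in the shorter list minus those only in the longer was set against random lists matched on number of peaks. It was 4 for sarcomere (percentile 99.8), 2 for excitation, membrane and fusion (96.9), 2 for the respiratory chain (98.9), 1 for glycolysis (91.2) and -1 for myogenic regulators (49.4). At the other end it was -4 for fibroblast genes (10.6), -2 for ribosomal proteins (8.12), -2 for neuronal genes (19.9) and -2 for secreted factors (30.2). With peaks of at least 250 bases in both lists, the difference was 0 for the respiratory chain, neuronal genes and ribosomal proteins, and it turned to -2 for glycolysis, 1 for myogenic regulators and 1 for secreted factors. Of these 9 lists, sarcomere (2 to 6), excitation, membrane and fusion (1 to 4) and fibroblast genes (-5 to -1) kept their sign in all 6 alternatives tried. All genes together also leaned to the longer list in the main count (435 against 1277). They did so in each alternative but the widest peaks (728 against 559). The negative sign of fibroblast genes therefore does not by itself set them apart. These counts are of 1 library against 1, and 13 lists were described.

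The last comparison concerned Csf3, which encodes G-CSF, the secreted factor named in the series title. The longer list, labelled without pyruvate, held 1 peak in a 2-kb flank of Csf3, at chr11:98561346-98561539 of mm9, and the shorter list held none within 10 kb. The files do not show whether this flank, 98560577 to 98562576, is upstream or downstream of the gene. The peak was 193 bases wide, at the 24.3 percentile of widths in its list. The longer list had a further peak 7760 bases from the flank, in Med24 (179 bases, chr11:98570336-98570515), and both lists shared a peak in Psmd3, 263 and 292 bases wide, at chr11:98543794-98544057 in the shorter. Within 50 kb the shorter list held 1 peak and the longer 3, and within 100 kb 3 and 4. Of the other secreted factor genes, Ctf1 and Angptl4 had a proximal peak in both lists, Fgf21 (275 bases) only in the shorter, and Fgf7 (239 bases) and Sparc (201 bases) only in the longer. Whether Csf3 differed between conditions had no test, because a narrow peak in 1 library has no measure of error.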

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

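The alternatives with located start sites alone, any peak in the gene, a width of 250 bases, the widest or a random subset of the longer list, and the RefSeq background were chosen after seeing the data. Of 53 alternatives for the main results 14 stayed within their bounds and 39 moved, and of 158 for single gene lists and the RefSeq background 96 stayed and 62 moved. The cause was not tested unless the construction shows it. Values are given for the list labelled with pyruvate, then without.

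Stricter overlap lowered the shared share to 68.2% and 42.0% (reciprocal 50%) or 69.0% and 42.5% (centres within 100 bases). With peaks of at least 250 bases, 5993 and 8832 peaks were left, 66.5% and 45.1% were shared, and 13.0% and 11.6% were promoter-proximal. Taking only the widest peaks of the longer list, as many as the shorter holds, 58.5% and 58.3% were shared; with a random subset, 44.3% of the shorter list was, as fewer peaks can be hit.

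Promoter-proximal peaks were 6.36% and 5.46% at 1 kb of located starts, 22.3% and 20.1% at 10 kb, and 8.57% and 7.54% with located starts alone. Genes in both, only the shorter and only the longer list were 567, 189 and 509 at 1 kb, 750, 224 and 669 with located starts, 3984, 720 and 2531 with any peak in the gene, and 572, 282 and 583 at 250 bases or more, against 1350, 435 and 1277. At 10 kb 2027 genes were in both. With the widest peaks of the longer list, 728 genes were only in the shorter and 559 only in the longer; with a random subset the means were 869 in both, 916 and 795 (ranges 858 to 962 and 748 to 835 over 100 draws), so the order turned at equal list length. Muscle genes of the 3 lists together were 7 to 12 only in the shorter and 1 to 6 only in the longer over 6 alternatives, nearest to each other at 10 kb (8 and 6). With the random subset they were on average 20.6 and 3.05. That subset also drops shared peaks, which by construction moves genes from both lists to the shorter alone, so these means do not strengthen the excess. Around Csf3 the shorter list had 0 peaks within 10 kb and 3 within 100 kb.

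Against the RefSeq background, 6 gene lists in place of 1 were above percentile 95 in the longer list, fibroblast genes (96.9) among them. The windows of 1 kb used located starts alone, and those of 10 kb reached only 2 kb upstream. Alternatives on q, fold enrichment, top peaks by q and E-boxes were not run. No paired analysis was possible because each condition has 1 library. Unknown depth limits every absent peak.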

Other observations

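All tests in this part, with the pathway and region counts, were chosen after the data were seen. Pygm, which encodes muscle glycogen phosphorylase, had 15 peaks centred within its body of 14.1 kb (chr19:6384399-6398459) in the longer list and 3 in the shorter, or 10.7 and 2.13 peaks per 10 kb. Among genes of at least 5 kb with at least 5 peaks in a list, the next densest, Iffo1, reached 4.23 per 10 kb, in the shorter list, and Cadm4, a cell adhesion gene, had 7 peaks in the longer list and 0 in the shorter. Counting peaks anywhere in the gene or its flanks, 13 glycolysis genes had one in both lists, 4 only in the shorter and 0 only in the longer, and sarcomere genes split as 23, 4 and 0.

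Unpartnered peaks were unevenly spread. The 1-Mb window with the most in the longer list was 99 to 100 Mb of chromosome 11, which holds Krtap4-9 and Krtap9-5, genes of hair keratin-associated proteins, with 30 against 2 in the shorter list. In the shorter list it was 80 to 81 Mb of chromosome 10, with 19 against 11. The longer list held 1.62 times as many peaks over all chromosomes. It held 2.186 times as many on chromosome X and 1.27 times as many on chromosome 7, which carries Ckm, Fgf21, Cox6a2 and Cox8b. Cox6a2 and Cox8b alone make up the respiratory chain difference of 2, and the matched random lists were not matched on chromosome. For 115 KEGG pathways, a peak anywhere in the gene or its flanks was counted, not only promoter-proximal ones, and differences were set against matched random lists. Oxidative phosphorylation stood highest (percentile 99, with 9 genes only in the shorter list and 10 only in the longer) and cardiac muscle contraction next (98.5). Axon guidance (2.0) and platelet activation (1.85) were lowest. With 4 pathways at or above percentile 97.5 and 3 at or below 2.5, where 2.88 each would be drawn by chance, the pathways as a family did not stand apart from chance.

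The first pattern is the longer list itself, labelled without pyruvate. Its peaks of at least 400 bases numbered 1794 against 1218, a ratio of 1.47. This count alone cannot show whether the extra peaks are only narrow, because most wide peaks overlapped the other list. In the longer list 81.4% of 1096 peaks of 400 to under 500 bases did, and 87.5% of 698 peaks of 500 or more. In the shorter list the shares were 86.5% of 735 and 91.5% of 483. Wide peaks without a partner were thus more numerous in the longer list, so its extra peaks were not only narrow ones. Its unpartnered peaks had a median width of 212 bases against 289 for partnered ones, and the widest had 1132 bases. Widths in the longer list piled up at 144 bases (290 peaks) and again at 160 bases (461 peaks), the second pile holding 4.56 times the mean of the 5 next widths. Among its 40 narrowest widths, the other list had a single pile at its minimum of 169 bases and otherwise no ratio above 1.39. A candidate explanation is that more than 1 calling run was pooled in the longer list, since a caller's minimum width follows its fragment length. Against a plain pool of runs, only 14 neighbouring peaks overlapped in the longer list and 3 in the shorter. Whether overlapping calls were merged or removed is not known. Differences in read depth or enrichment, and pyruvate itself, stay open and untested.

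The second pattern is muscle genes with a proximal peak only in the shorter list, taken over the myogenic, sarcomere and excitation lists together, 10 genes against 5 only in the longer. List length alone is argued against, since random lists matched on number of peaks had a median difference of -4 and a maximum of 7, which puts the muscle genes at percentile 99.89. The 3 lists were pooled after their counts were seen. The percentile reuses the counts that defined the pattern, so it is not independent support for it. Of ribosomal protein genes 0.0% had a proximal peak in the shorter list, which argues against signal at every highly transcribed gene. It covers 1 gene family, and 26.7% of glycolysis genes had such a peak. Signal at other highly transcribed genes stays open, and transcription was not measured. The excess was 8 against 6 genes with the 10-kb window. With peaks of at least 250 bases in both lists it was 11 against 1, but the width cutoff shapes that count. It removes Myh3, Actc1, Cav3 and Ckm (232, 220, 217 and 190 bases) from the 10, and also Myom2, which ranked below Actc1 by width. The 11 therefore include genes with a narrower proximal peak in the longer list. Peaks near the detection limit that 1 library missed, and a stronger occupancy with pyruvate, both stay open. The 13 proximal peaks concerned had a median width of 259 bases, close to the 258 of the shared proximal peaks of the shorter list. That was 51.0 above the 208 of its other unpartnered proximal peaks (percentile 98.1 among random draws of 13). The 13 peaks came from 10 genes, 3 of them from Acta1, and the draws of single peaks did not match this.

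The third pattern is the row of peaks along Pygm in the longer list. A gain of the genomic region reaching past the gene is argued against, since the 10 kb on its sides held 0 and 1 peak centres, and the denser side had 9.37% of the density of 10.7 per 10 kb within the gene. The 1 peak beside it lay across the gene's end and overlapped a peak of the shorter list. Whether the peaks follow the exons, as DNA copied from Pygm transcripts could give, was not tested, because exon positions were not used here. No biological explanation was tested.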
